A study of Caenorhabditis elegans with 4 samples.

How the data were processed

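The series held 4 libraries from wild-type N2 hermaphrodites at the L2 stage, 2 of input DNA and 2 of ChIP DNA, grouped by the channel text of their descriptions and numbered by the replicate in their titles. Replicates came from separate extractions, per the labels. The labels' protocols describe growth in liquid culture at 20 °C with bacteria as food, formaldehyde crosslinking, sonication, immunoprecipitation, size selection on a gel and Illumina sequencing. The shared protocol text speaks of embryos and of an anti-GFP serum, whereas the descriptions of the ChIP libraries name the Pol II antibody 8WG16 and the stage label is L2. The antibody and the stage are taken here from the descriptions and the characteristics.

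The file analysed was one combined peak list. Peaks were called with PeakSeq on the WormBase WS210 build, per the file headers and the source column. The deposited q value of each peak is the authors' own, stands in the score column and is repeated as an attribute in all 1888 records. Starts and ends were used as deposited, counted from 1. The aligner, the version and thresholds of PeakSeq, the read numbers and the way both replicates were combined are not given in the sources used here. Depth per library is therefore unknown.

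Recovered counts. The q values were turned back into p values. Within runs of equal p, q falls as the rank rises, and all 128 such places with a whole-number solution gave the same offset of 42 ranks before the first peak. The number of tests was the whole number for which most p values were binomial tails of whole count pairs with probability 0.5: 15045, with 375 peaks in favour and 3 for the next best number. At a relative tolerance of 1e-09, 1880 peaks (99.6%) had one count pair, 3 had several and 5 had none. Totals of up to 30000 tags were searched, except for the peaks of lowest p, where the search stopped at a lower total. Of pairs of up to 1000 tags, 1372 matched, and 0 matched with the offset or the number of tests changed by 1. The larger count was taken as ChIP and the smaller as scaled input. PeakSeq compares tags in this way, but this reading is an inference from the numbers. Fold is ChIP over scaled input. Its 95% interval is the exact (Clopper-Pearson) interval of the share of ChIP tags among ChIP tags and input tags before scaling (Input factors), carried over to the ratio and divided by the factor of the chromosome. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only.

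Input factors. The input counts of each chromosome were tested for a common factor, which is read here as the scaling of the input, an inference from the numbers that the sources used here do not state. For each chromosome, factors from 1.3 to 5 in steps of 0.0005 were scanned for the one whose rounded-up multiples held the most input counts beyond the share of whole numbers that they make up. On the 6 chromosomes 88.2% to 97.3% of the counts lay on such multiples, where 31.7% to 49.9% of whole numbers are such multiples. A scan picks the best factor and so exceeds that share even without one: after each count had been raised by a random 0 to 3, the scan found 44.8% to 61.2% on multiples. The smallest z score was 15.8 for the counts as recovered, and the largest was 6.27 after the random shifts. The count before scaling was taken as the input divided by the factor, rounded down. For comparisons on one scale, the highest factor, 3.16, was applied to every chromosome, the binomial p was recomputed, and regions at or under the list's largest p of 0.00128 were kept. Median folds at this factor were taken both over these regions and over all listed regions, since a p limit that depends on fold keeps a different share of each chromosome. The highest factor was chosen because regions can then be lost but none that the list lacks would be needed.

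Positions. Chromosome length was the span from the first to the last peak, since no table of WS210 lengths was used. X was compared with the 5 autosomes by an exact permutation of the 6 chromosomes (smallest p 0.167). Central and outer parts were compared by an exact sign-flip test over the 6 chromosomes (64 flips). Distances between neighbours were compared with 1000 random placements without overlap, and correlations across peaks used 100000 permutations. All tests were two-sided, and the 4 planned p values were adjusted together by the Benjamini-Hochberg method. Medians per chromosome and the ratio of chromosome I to the others carry 95% intervals from resampling 1 Mb blocks (2000 draws; 500 for differences of log2 fold).

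The regions named were fixed before the data were examined: the 15 with the lowest q, the best of each chromosome and the 3 widest. Densest windows, regions of highest fold with at least 100 ChIP tags, all results from recovered counts and factors, and the ratio of chromosome I to the others were chosen after the data were seen. Alternatives were stricter lists, merging within 500 or 2000 bp, leaving out narrow peaks or chromosome I, a floor of 250 ChIP tags per kb, other lengths and distances, and the common input factor.

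The gene table used here is of the assembly WBcel235, whose coordinates are not those of WS210. Planned comparisons of peaks with genes and with 35 gene lists were therefore not run, and no gene is assigned to a region. Recovery was tested on 15000 simulated regions, where 150 of 150 count pairs and the true offset at 22 of 22 ties were recovered. The count pairs were recovered with the true offset and number of tests supplied, so the search for the number of tests was not simulated. Only pairs of limited total were tried, and their input had no factor. A simulated factor of 2.7 was found as 2.7 from 250 values (100% on multiples, z = 20.6), and 250 values simulated without a factor gave 64.4% on multiples (z = 3.74). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.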

Results

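RNA polymerase II (Pol II) occupancy was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Caenorhabditis elegans hermaphrodites of the N2 strain, harvested at the second larval stage (L2) after growth at 20 °C. The labels give 2 ChIP libraries made with 8WG16, a mouse monoclonal antibody against the heptapeptide repeats of the C-terminal domain of the largest Pol II subunit AMA-1, and 2 libraries of input DNA, the unenriched chromatin that serves as background. Both replicates entered a single combined list of called regions (peaks), each with a start, an end and a q value, so no value belonged to one library and no spread between replicates could be given. The list addressed where in the genome Pol II was bound at this stage. All positions are those of the WormBase WS210 build, counted from 1. The gene table used here follows another assembly, so regions are given by position, without gene names or exon and intron annotation.

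In the list, Pol II occupied 1888 separate regions that covered 3544.7 kb, or 3.56% of the 99.5 Mb between the first and the last peak of the 6 nuclear chromosomes. The ranks recovered from the q values put 42 regions before the first of the list, and these totals leave them out. The 1888 regions had a median width of 1048.5 bp, with an interquartile range of 469 to 2611 bp. Broad domains made up much of the covered length: 156 regions of 5 kb or more held 32.1% of it, and 21 spanned 10 kb or more. The widest was III_7718209, named here by chromosome and start, which ran for 20688 bp on chromosome III from 7718209 to 7738896. The next were III_343324, from 343324 to 358074 (14751 bp), and IV_14610406, from 14610406 to 14624612 (14207 bp). At the other end, 32 regions were narrower than 20 bp, 18 of them on chromosome I, and 3 were a single base. The authors' q values ran from 2.45e-304 to 0.00999973, with a median of 2.05e-06.

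**Figure D1:**
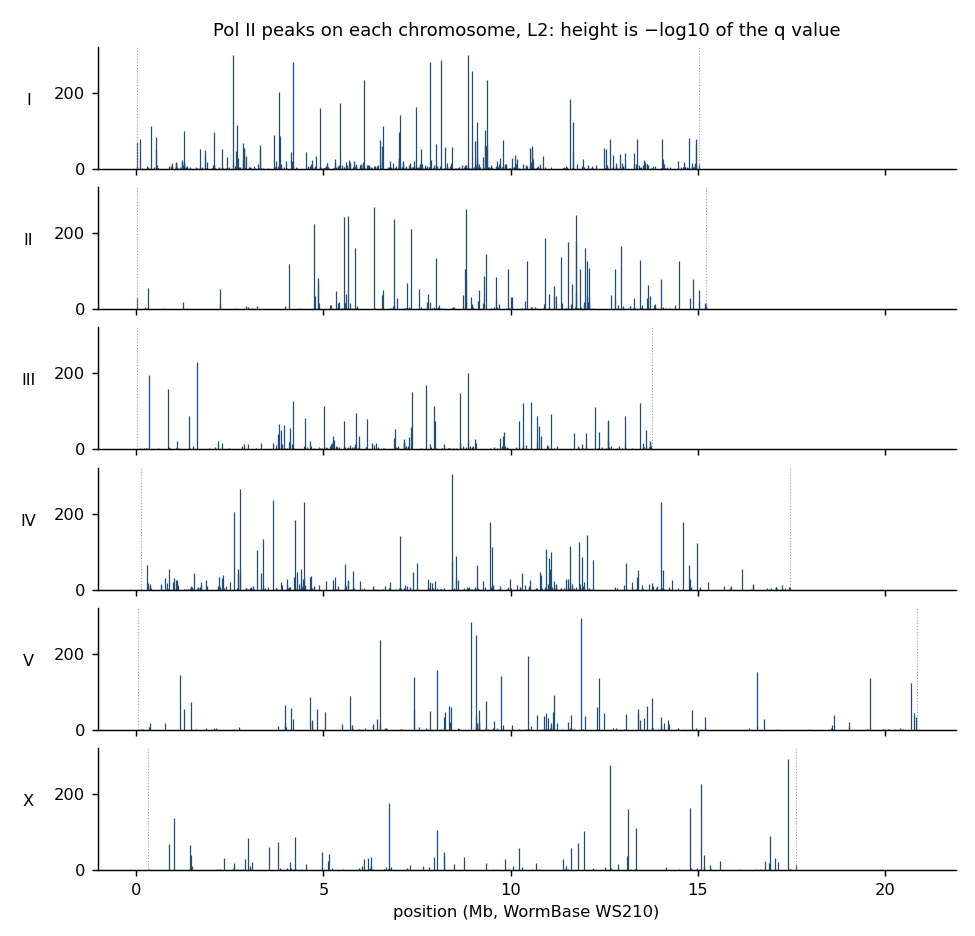
Position (x axis, Mb, WormBase WS210) and −log10 of the authors' q value (y axis) of each of the 1888 Pol II peaks on the 6 chromosomes; dotted lines mark the first and last base covered. Chromosome I carries the most lines (642 peaks), and peaks near the top of the scale stand on I, IV, V and X.

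The q values held the tag numbers behind the peaks. Each q was a p value times 15045 tests divided by a rank, and 1880 of the 1888 p values equalled the one-sided binomial tail of a single pair of whole numbers. The larger number is read here as the ChIP tags and the smaller as the scaled input tags of the region, a reading that the sources used here do not state. ChIP tags per region ranged from 18 to 6834 with a median of 246, and scaled input tags had a median of 136. The median enrichment over input was 1.90-fold, with an interquartile range of 1.59 to 2.46 (n = 1880 regions). Enrichment reached 2-fold in 825 regions (43.9%) and 4-fold in 92 (4.89%), whereas 337 (17.9%) lay under 1.5-fold. Library totals are unknown, and the 95% intervals of single folds cover counting error only, with the input counted before its inferred scaling.

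**Figure D2:**
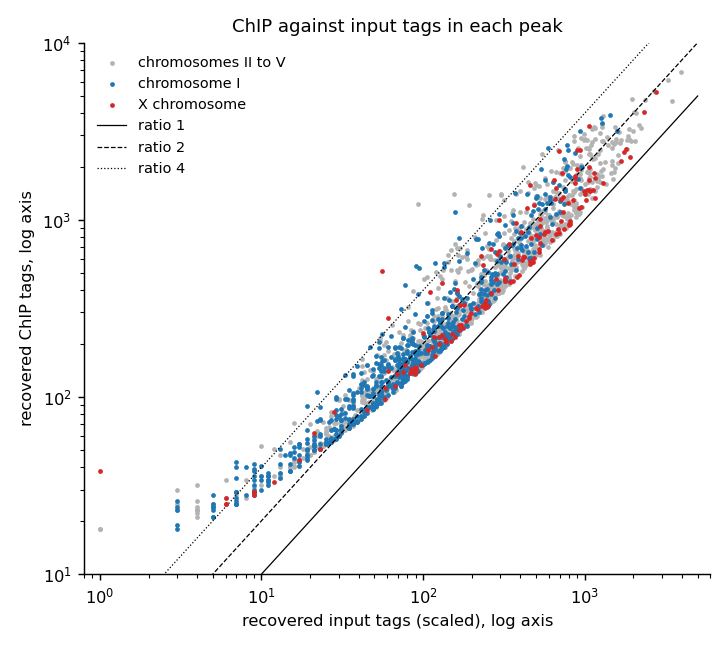
Recovered ChIP tags (y axis, log scale) against recovered scaled input tags (x axis, log scale) for each of the 1880 peaks with a single count pair, coloured by chromosome; lines mark ratios of 1, 2 and 4. Most peaks lie between the ratios 1 and 4, with a median of 1.90, and weak folds pass only where tags are many.

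The 15 regions with the lowest q values in the list came from I (6), II (2), IV (2), V (3) and X (2). The lowest q belonged to IV_8429709, on chromosome IV from 8429709 to 8433850 (q = 2.45e-304), followed by I_2579959, on I from 2579959 to 2588860 (q = 1.71e-299), and I_8864926, from 8864926 to 8869364 (q = 3.34e-299). V_11887705, from 11887705 to 11890042, and X_17419525, from 17419525 to 17424856, led their chromosomes. The p values of these 5 regions had too few digits to yield tag numbers. Among the others, I_8133195 (8133195 to 8136614) held 2552 ChIP tags against 589 scaled input tags, a 4.33-fold enrichment (95% interval 3.84 to 4.91). II_8819274 (8819274 to 8821555) reached 4.31-fold (3.70 to 5.07), and II_6342665 (6342665 to 6349687), the best region of chromosome II, reached 2.46-fold (2.26 to 2.68) from 4797 ChIP tags. On X, X_12662048 (12662048 to 12669310) had 3394 ChIP tags and was 3.18-fold enriched (2.86 to 3.54). The best region of III, III_1615903 (1615903 to 1627083), had 3472 ChIP tags and was 2.73-fold enriched (2.47 to 3.02). These folds rest on input scaled differently on each chromosome, as inferred from the recovered numbers. With one input factor of 3.16 on every chromosome, I_8133195 was 2.75-fold enriched, X_12662048 2.78-fold, III_1615903 2.57-fold, II_8819274 4.32-fold and II_6342665 2.46-fold.

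V_9088558 differed from the rest of this group in shape. It spanned 764 bp, from 9088558 to 9089321 on chromosome V, held 1222 ChIP tags against 93 scaled input tags, and was 13.1-fold enriched (9.20 to 19.6). Its 1599 ChIP tags per kb were the highest density among the 1378 regions of 500 bp or more with recovered tags, whose median was 248 tags per kb. The widest region of the list, III_7718209, held 330 tags per kb and was 1.73-fold enriched (1.63 to 1.83). The ranks show a limit of the list: its first region held rank 43, so the 42 regions ranked before it were not analysed here.

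Wider regions had lower q values. Width and −log10 q correlated across the 1888 regions with a Spearman rho of 0.661 and a Pearson r of 0.543 (permutation p = 1e-05 for each, the smallest that 100000 permutations give; Benjamini-Hochberg adjusted p = 4e-05 for rho over the 4 planned tests). Regions of 5 kb or more had a median enrichment of 1.75-fold, and the 505 regions under 500 bp one of 2.32-fold. Regions are not independent replicates, and a binomial p falls as tags accumulate along a region, so width and q are linked by construction. A region with few tags passes the q limit only at a high fold. The contrast in fold by width is therefore partly set by the calling.

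Chromosome I carried the most regions. It held 642 of the 1888 (34.0%), or 42.7 per Mb, compared with 22.7 per Mb on IV, 20.7 on III, 14.7 on II, 9.19 on X and 8.94 on V. The ratio of chromosome I to the mean of the other 5 was 2.80, with a 95% interval of 2.08 to 3.59 from resampled 1 Mb blocks. Regions on I were the narrowest, with a median width of 637.5 bp against 1093.5 bp on III, 1132 bp on IV, 1518 bp on II, 1691.5 bp on V and 2428 bp on X. In base pairs covered, I led with 53.1 kb per Mb, ahead of IV (42.6), III (42.4), II (32.4), X (26.1) and V (23), a ratio of 1.59. Among the 472 regions of lowest q, the ratio was 1.76. The excess was smaller on a common input scale. On each chromosome, 88.2% to 97.3% of the recovered input numbers were rounded-up multiples of one factor, which was 2.00 on I, 2.44 on IV, 2.76 on X, 2.97 on III, 3.09 on V and 3.16 on II. These factors are read here as a scaling of the input for each chromosome, an inference from the numbers that the sources used here do not state. Under that reading, with the factor of 3.16 on every chromosome, 1159 of the 1880 regions stayed at or under the list's largest p, 0.00128. Chromosome I then held 220 regions, or 14.6 per Mb, below III with 17.4 and close to II with 14.7, and the ratio fell to 1.26 (0.93 to 1.67). The highest factor raises the input most on I, so a fall of the ratio was built into this choice.

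**Figure D3:**
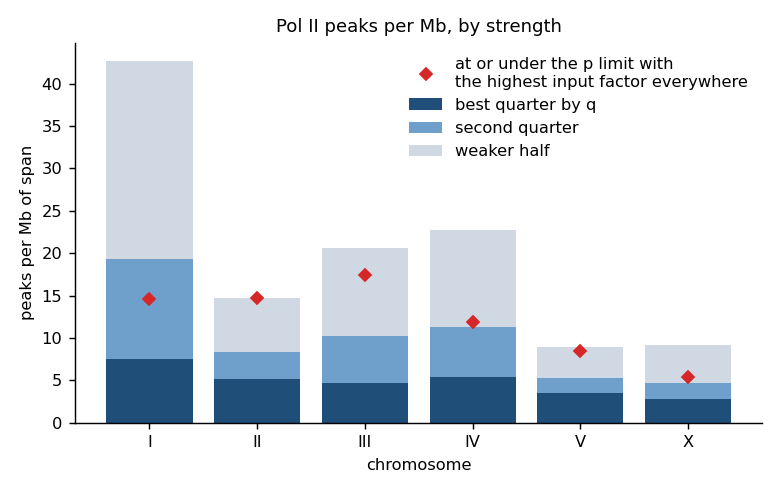
Peaks per Mb of span (y axis) on each chromosome (x axis), stacked by strength from the best 472 of the list by q at the bottom, through the rest of the best 944, to the others at the top; diamonds mark the peaks per Mb that stayed at or under the list's largest p with the highest input factor on every chromosome. The stack of chromosome I reaches 42.7 and its diamond 14.6, and X has the lowest diamond at 5.43. The highest factor keeps a smaller share of regions where the listed factor was smaller, so the order of the diamonds is partly built in.

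The X chromosome held few regions. It had 159 regions (8.42% of the list, Wilson 95% interval 7.25% to 9.76%), and its 9.19 per Mb compared with a mean of 21.9 ± 12.8 per Mb (SD, n = 5 autosomes), a ratio of 0.419. The Wilson interval treats regions as independent, which they are not, and does not cover the spread between chromosomes. In base pairs covered per Mb, where the broader regions of X count for more, the ratio was 0.675 (exact permutation p = 0.5), and without chromosome I the ratio of region numbers was 0.549 (exact permutation p = 0.6). Chromosome V was sparser still, and the exact permutation test over the 6 chromosomes gave a two-sided p of 0.5 (adjusted p = 0.5), where the smallest possible is 0.167. With one input factor on every chromosome, X had the fewest regions per Mb (5.43, followed by V with 8.51), a ratio of 0.405 and that smallest p of 0.167 in the exact test. Enrichment as listed was also lowest on X, with a median of 1.57-fold (95% block-bootstrap interval 1.5 to 1.67), compared with 2.10 (2.03 to 2.15) on I, 1.86 (1.80 to 1.93) on IV, 1.85 (1.73 to 1.94) on II, 1.81 (1.69 to 1.90) on V and 1.77 (1.73 to 1.90) on III. The ratio of X to the mean of the autosomes was 0.834 (exact permutation p = 0.333). With the common factor, the order depended on the regions counted. Over all listed regions the medians were 1.34 on I, 1.37 on X, 1.44 on IV, 1.67 on III, 1.78 on V and 1.86 on II, with I and not X the lowest. The highest factor lowers the folds of I most, so this fall of I was built into the choice. Over the regions still at the p limit (34.4% of those on I, 59.5% on X and 100% on II), they were 1.61 on X, 1.68 on IV, 1.73 on III, 1.74 on I, 1.78 on V and 1.86 on II. A chromosome-level difference of the X could not pass a threshold of 0.05 in this design.

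**Figure D4:**
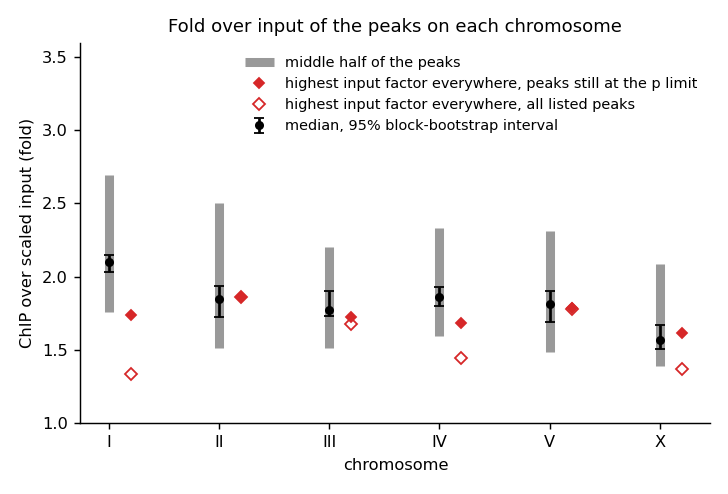
Enrichment of ChIP over scaled input (y axis, fold) on each chromosome (x axis): dots are medians with 95% block-bootstrap intervals, grey bars the interquartile range, and diamonds the medians with the highest input factor on every chromosome, open over all listed peaks and filled over the peaks still at the p limit. X has the lowest dot, 1.57, and filled diamond, 1.61, whereas chromosome I has the highest dot, 2.10, and the lowest open diamond, 1.34.

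The middle of the chromosomes held more than an even share of regions on 5 of 6, without passing the test. The middle one of 3 equal parts held 49.5% of the regions on V, 48.4% on I, 47.9% on III, 43.5% on II and 35.8% on IV, all above the 33.3% of an even spread, and 32.7% on X. The mean was 43% ± 7.12 (SD, n = 6 chromosomes), 9.63 percentage points above an even spread (exact sign-flip permutation p = 0.0625, two-sided; adjusted p = 0.0833; smallest possible p 0.0312). On 3 chromosomes an outer part held more regions than the middle: on II the right part had 102, the middle 97 and the left 24, on IV the left had 170, the middle 141 and the right 83, and on X the left had 54, the right 53 and the middle 52.

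Regions also lay closer together than under random placement along each chromosome. The median distance from the end of a region to the next start was 17522 bp, compared with 28309 bp when regions of the same widths were placed at random (range of 1000 placements 25581 to 30588 bp), a ratio of 0.619. The permutation p was 0.002, two-sided, the smallest that 1000 placements give (adjusted p = 0.004). Placement was uniform along each span, so uneven density over long stretches, such as more regions in the middle, also shortens these distances. The test cannot tell local clustering from such unevenness. In the list as deposited, the 1 Mb stretches with the most regions were on chromosome I, with 88 between 7 and 8 Mb, 71 between 9 and 10 Mb, 60 between 5 and 6 Mb and 50 between 6 and 7 Mb, followed by III with 48 between 5 and 6 Mb. With the input factor of 3.16 on every chromosome, III from 5 to 6 Mb led with 38 regions, ahead of I from 7 to 8 Mb with 33 and IV from 11 to 12 Mb with 29. That factor kept 34.4% of the regions on I, against 84.5% on III, so a fall of I in this order was built in. By covered length, the fullest 100 kb window was on chromosome II from 12 to 12.1 Mb, where 9 regions covered 29.5 kb, followed by X from 11.4 to 11.5 Mb, where 5 regions covered 28.2 kb. These 2 windows differed in enrichment, with medians of 2.15-fold on II and 1.28-fold on X. Among the 472 regions of lowest q, the ratio of distances was 0.906 (permutation p = 0.0519), which no longer passed the threshold of 0.05.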

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

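The alternatives with 2000 bp merging, without chromosome I, with a tag floor, with the length from base 1, with raised input and with one input factor were chosen after the results were seen, as were the fold and chromosome I results. Of 74 alternatives to the principal results, 60 kept the direction and the side of the threshold or stayed within the spread, and 0 reversed. This count is a weak sign of stability, because many alternatives had little room to differ. Those of the X comparisons could not pass 0.05 (smallest p 0.167). Width and q are linked by construction, and the p limit required a fold above 1. The number of regions was 944 or 472 in the stricter lists by q, 1246 without chromosome I, 674 with at least 250 ChIP tags per kb and 1159 with the highest input factor on every chromosome, each smaller by construction. The central excess of 9.63 points passed the exact sign-flip test with p = 0.0312 without regions under the 10th percentile of width (9.84 points), with the tag floor (14.3) and with the length from base 1 (10.01); the cause was not tested. The exact sign-flip p rose from 0.0625 to 0.0938 in the list of 472 (7.19 points). It rose to 0.125 with one input factor (8.35 points) and without chromosome I (8.53 points). The central excess kept its direction over all its alternatives. The call of shorter distances than under random placement was lost in the list of 472 (ratio 0.906, permutation p = 0.0519), which holds fewer regions. The effect was also smaller there than in the full list (ratio 0.619). It shrank too in the list of 944 (0.836), after merging within 2000 bp (0.840) and with one input factor (0.765). In each of these the permutation p was 0.002. The ratio of chromosome I to the others, 2.80, was 2.31 after merging within 2000 bp, 1.76 in the list of 472, 1.68 with the tag floor, 1.59 in covered base pairs and 1.26 with one input factor. Of 20 named regions with a fold, 19 had the same fold before and after merging within 500 bp. Merging therefore could not test the stability of these 19. Only I_5431166 changed, from 7.03-fold to 4.39-fold, and it left its interval. With one input factor, 10 of the 19 named regions with a fold at that factor left their interval. Among them were all 6 on chromosome I, whose folds became 0.634 to 0.636 of those listed. No paired analysis was possible because the list combines both replicates and carries no value per replicate, and leaving out a replicate was not possible either. The alternatives for genes and gene lists were not run, since the gene table is of another assembly. Depth per library is unknown, so regions under the limit of detection cannot be bounded.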

Other observations

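All tests in this part, and the choice of regions by fold, came after the data were seen; the tests with one input factor were fixed before their own values were computed. Among regions with at least 100 ChIP tags, the 6 most enriched at the input factors as listed included a pair on chromosome II. These were II_11756360 (11756360 to 11757257, 8.99-fold, 95% interval 6.78 to 12.2) and II_11761570 (11761570 to 11762438, 6.27-fold, 4.86 to 8.28). Both were under 1 kb wide and held 1393 and 1211 ChIP tags. On chromosome I, I_5431166 (5431166 to 5433239) was 7.03-fold enriched (5.61 to 9.003; 4.39-fold after merging with regions within 500 bp) and I_14058440 (14058440 to 14059064) 6.04-fold (4.5 to 8.47). With the highest input factor the folds of I_5431166 and I_14058440 as listed became 4.47-fold and 3.85-fold, while V_9088558 (9088558 to 9089321) went from 13.1-fold to 12.9-fold. Both regions of chromosome I were then below II_5543303, which had 4.77-fold as listed on the chromosome with that factor.

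X_16933704 (16933704 to 16935442) was the most enriched region of X with that many tags, at 9.13-fold (5.94 to 15.3), or 7.98-fold with the highest input factor. Its input differed from that of the others: 56 scaled tags (20 before scaling), or 32.2 per kb, the lowest density among the 1378 regions of 500 bp or more with recovered tags, whose median was 141 per kb. Its 294 ChIP tags per kb were near the median of 248. A second region lay close by, X_16936686 (16936686 to 16936752, 67 bp), with 38 ChIP tags and 1 scaled input tag (0 before scaling, rounded down). Its 567 ChIP tags per kb cannot be set against the median of 248, which is for regions of 500 bp or more.

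For the excess of regions on chromosome I, 2.80 times the mean of the other 5, the values argue against long domains split by gaps of up to 2000 bp as the whole cause: after merging within 2000 bp the ratio was 2.31 (95% interval 1.78 to 2.83), above the bound of 1.2 set for this explanation. Pieces with wider gaps between them were not joined, so splitting at such gaps was not tested. A lower limit on tag density stays open, since the ratio was 1.68 (1.02 to 2.51) among regions of 500 bp or more with at least 250 ChIP tags per kb. The factor read as the scaling of the input, which no source used here states, was smaller on chromosome I, 2.00 against 2.44 to 3.16 elsewhere. If that reading holds, it may account for some or all of the excess, and stays open as the whole cause. With one factor the ratio was 1.26 (0.93 to 1.67), an interval on both sides of 1.2. The highest factor raises the input most on chromosome I, where 34.4% of regions were kept, against 100% on II. A fall of the ratio was thus built into this choice, and whether one factor is the right scale for every chromosome could not be tested. No biological explanation was tested, since the design has no second condition.

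The lower enrichment on X, a log2 difference of -0.26 from the mean of the autosomes, was weighed in the same way. Broader regions on X left a difference of -0.14 (95% interval -0.21 to -0.06) over 5 width classes. Among the listed regions, at the input factors as listed, part of the difference thus remained within width classes. These regions were themselves chosen by a p limit that fold decides, so the part of width stays open. One input factor left -0.12 (-0.22 to -0.04) over the regions still at the p limit and -0.23 (-0.29 to -0.13) over all listed regions. Both sets were chosen by a limit that fold itself decides, so the part of the factor stays open. In the second set I lay below X, but the smaller factor of I built this order in, so it tells nothing of the cause. With width classes and one factor together the difference was -0.032 (-0.13 to 0.09) in the first set and -0.12 (-0.18 to -0.04) in the second, which leaves this open too. Dosage compensation in hermaphrodites, which lowers transcription from both X chromosomes, was not tested.

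The first region of the list held rank 43, and its p value, 7e-307, was close to 2.23e-308, the smallest number that double precision holds in normal form. This is consistent with regions of still smaller p having been left without a number and so out of the list, a hypothesis drawn from the same values. The 42 regions that would rank first were not analysed here, so the strongest sites of Pol II in these larvae may not be among those named.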
